A study of Homo sapiens with 6 samples.

How the data were processed

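Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA, in HCT116 cells, an established human colon cancer line. The 6 libraries, 3 from NuMA-depleted and 3 from wild-type cells, each had 1 deposited peak list. Groups were taken from the genotype label of each sample. The labels do not say whether replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

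Per the submitters' processing notes, reads were handled with Trim Galore, Bowtie2 (version 2.4.1) and Picard on build hg19. The peak names inside the deposited files record a macs2 folder and the word combine, whose meaning is not given in the sources used here. The peak caller's version and settings, the read filters, any read shift for the transposase and any removal of artefact-prone regions are not given in the sources used here. Peaks were called per sample, since each file belongs to 1 sample. For each peak the deposited files give the interval, the summit, the fold enrichment over the caller's local background (a linear ratio), the −log10 p-value and the −log10 q-value, and a score. The deposited score follows 10 times the −log10 q-value, written as a whole number, and was not used separately. The smallest −log10 q in any list was 2.00, so the authors' lists hold peaks with q of up to 0.01. All rows lay on chromosomes 1 to 22 and X, no interval was listed more than once in a library, and no row was left out. A fold or q of a peak belongs to its own library. Both served to describe, rank or filter peaks within a list. Regions called in several libraries were also ranked by their weakest q, and their folds given as a mean and SD, range or median over libraries. The fold also served to recover depth. These values are not on a scale known to be common to the lists.

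The files hold no read totals. Relative depth was recovered from each peak's fold and p-value under a Poisson model of the fragment pileup. With a tolerance of 0.01 on the −log10 p scale, a whole-number pileup was found for 99.977% to 99.991% of the peaks of each library. The smallest background of a library, in fragments, divided by its smallest peak width, was taken as proportional to depth. This assumes that the smallest width equals the fragment length the caller used, which the sources do not state. Depth in reads remained unknown.

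From the files, the number of peaks, the length under peaks, the median peak width and the percent of peaks whose gap to the next peak was under 1 kb were computed per library. Group means were compared with an exact permutation test, two-sided. With 3 libraries against 3 there are 20 assignments, and the smallest p it can give is 0.10. The 6 lists were merged at an overlap of at least 1 bp, and each merged region was scored as called or not called in each library. Regions called in all 3 libraries of a group and in none of the other were counted and set beside the same count for the 18 sets of 3 libraries that mix the groups. Single regions were not tested, since no test of 3 against 3 on presence can go below 0.10. Overlap between libraries was the Jaccard index in bp. Peaks per 1 Mb bin, placed by summit, were tested with limma 3.58.1 in R 4.3.3 on log2 of the share of the library's peaks (pseudocount 0.5, moderated with a mean trend) in bins with a mean of at least 5 peaks, with Benjamini-Hochberg adjustment and a threshold of 0.05. Counts for this comparison of 1 Mb bins were also simulated, each drawn independently from a Poisson distribution. In them, 52.9% of 191 bins changed 2-fold were recovered, with 4 false calls, among 2011 bins tested. Of 183 bins changed 4-fold, 98.4% were recovered, with 13 false calls, among 2003 tested. Counts in the real lists need not vary as Poisson counts do, so these rates do not give the power on the real lists. Shares of peaks per chromosome were compared with the exact permutation test over 23 chromosomes. Other computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6.

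Tests, samples, alternatives and the rule for the regions named were fixed before the data were examined. The rule named, in each direction, the 12 regions with the highest weakest −log10 q among the 3 libraries that called them, and bins past the threshold. Alternatives were a −log10 q of at least 5, equal numbers of peaks per library (the strongest by −log10 p, as many as the smallest list holds), autosomes only, a 5 kb gap, a presence in at least 2 of 3 libraries, a stricter overlap, bins of 5 Mb or 250 kb, a pseudocount of 2, no filter on bins, a replicate block and leaving out each library. Windows of 500 bp on summits, common width and gap limits, a −log10 q of at least 15, mixed thresholds for presence and absence, cover of 50% of the merged region, distances between summits, widths above the smallest width, and combinations with equal numbers or with the replicate block were added after seeing the data. The division of the mixed sets by NuMA-depleted replicate 3 was not planned either.

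Results that need genes were planned and not run, because no hg19 gene annotation was used here and coordinates were not converted between builds. These are promoter shares, counts of gene promoters, 18 gene lists and the peak calls at the targeted gene, so the depletion itself was not checked here. Regions are therefore given by hg19 position without a gene, exon or intron.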

Results

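ATAC-seq peak lists were compared between NuMA-depleted and wild-type HCT116 cells, with 3 libraries per group. NuMA is a nuclear protein of the interphase nucleoskeleton that also organises the mitotic spindle poles, and the series asks whether it maintains local chromatin architecture. The lists of NuMA-depleted replicates 1, 2 and 3 held 38466, 45892 and 21783 peaks. Those of wild-type replicates 1, 2 and 3 held 35502, 38685 and 32503. Relative depth, on a scale where the mean of the 6 libraries is 1, was 1.07, 1.21 and 1.11 in the NuMA-depleted libraries and 0.975, 0.869 and 0.762 in the wild-type libraries. All 3 NuMA-depleted libraries were thus deeper than all 3 wild-type libraries.

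The number of called peaks and the length under them did not differ between the groups beyond the spread of the libraries. As the NuMA-depleted libraries were all deeper, this does not show equal amounts of accessible chromatin. NuMA-depleted libraries had 35380 ± 12347 peaks (SD, n = 3) and wild-type libraries 35563 ± 3091 (SD, n = 3), with p = 0.9 (exact permutation test, two-sided). Peaks covered 20.1 ± 8.70 Mb (SD, n = 3) in NuMA-depleted and 18.7 ± 1.03 Mb (SD, n = 3) in wild-type libraries, with p = 0.7 in the same exact test. The spread came mostly from NuMA-depleted replicates 2 and 3, which had the most and the fewest peaks of all 6 libraries and covered 28.4 and 11.1 Mb. Without NuMA-depleted replicate 3 the difference in peak number turned to 6616 more peaks in NuMA-depleted libraries (exact p = 0.4, with 2 against 3), and without wild-type replicate 2 to 1378 more (exact p = 1). Without NuMA-depleted replicate 2 the covered length turned to 2.88 Mb less in NuMA-depleted libraries (exact p = 0.8).

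**Figure D1:**
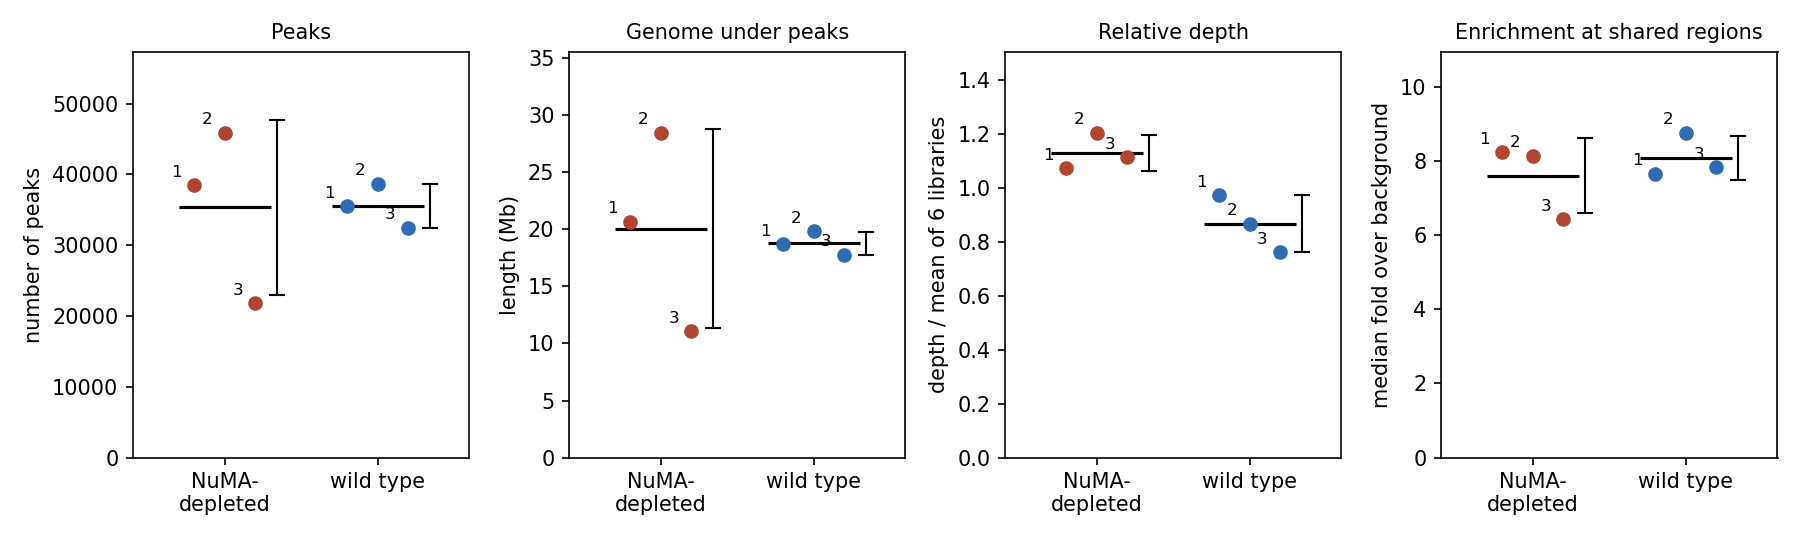
Number of peaks, genome length under peaks (Mb), depth relative to the mean of the 6 libraries, and median fold over background at the 17009 regions called in all 6 libraries, for each library (points, numbered by replicate), with the group mean (line) and SD (error bar). NuMA-depleted replicate 3 has the fewest peaks, 21783, and the lowest median fold, 6.43, at a relative depth of 1.11.

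Part of the accessible regions was called in both conditions. The 6 lists merged into 58926 regions, of which 17009 (28.9%) were called in every library, 14800 (25.1%) in a single library and 27117 (46.0%) in 2 to 5 libraries. A further 5122 regions were called in every library except NuMA-depleted replicate 3. The regions called in all 6 libraries had a median width of 914 bp and spanned 16.5 Mb. The strongest of them, by the weakest −log10 q among the 6 libraries, lay on chromosome 1 at 91852779 to 91853142 (hg19, as all positions here), where the fold over background, each list's own value, ranged from 21.8 to 25.9 over the 6 libraries. The next was on chromosome 1 at 156186242 to 156186598, with folds from 18.9 to 21.7. On chromosome 21, at 9826902 to 9827553, folds ranged from 4.84 to 7.39. On the X chromosome, at 108297383 to 108297830, folds ranged from 28.7 to 34.6 over the 6 libraries. The longest region shared by all 6 libraries covered 3379 bp on chromosome 17 at 46100787 to 46104165, with folds from 4.38 to 5.66. These shared regions were picked as the strongest and longest after their values were seen. Regions prone to mapping artefacts were not screened out here, so some of the strongest may be artefacts rather than open chromatin.

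A small set of regions was called in every NuMA-depleted library and in no wild-type library. There were 368 of them, on all 23 chromosomes, with a median width of 548 bp and a median of the mean fold of 5.77. The libraries that called them were also the 3 deepest. The strongest lay on chromosome 20 at 19796113 to 19796505, with a fold of 10.9 ± 0.908 (SD, n = 3) over background. It was followed by chromosome 18 at 57382979 to 57383484, with a fold of 9.45 ± 0.956 (SD, n = 3), and chromosome 8 at 38970322 to 38970854, with a fold of 10.5 ± 2.19 (SD, n = 3). On chromosome 3 the region at 148897730 to 148898292 had a fold of 10.1 ± 1.45 (SD, n = 3), and on chromosome 13 the region at 78711737 to 78712277 had a fold of 8.68 ± 0.457 (SD, n = 3). Chromosome 1 held 2 of the 12 strongest, at 159966363 to 159966752 and at 209212736 to 209213421. The others were on chromosome 7 at 47521596 to 47522336, chromosome 18 at 8121990 to 8122753, chromosome 15 at 57862968 to 57863778, chromosome 22 at 39114343 to 39114771 and chromosome 5 at 159276716 to 159277533. Over the 12, folds in single libraries ranged from 6.43 to 13.5. A region absent from a list did not pass the caller's threshold there, which does not show that it was closed.

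A similar number of regions, 349, was called in every wild-type library and in no NuMA-depleted library, again on all 23 chromosomes. Their median width was 478 bp and the median of the mean fold 5.82. The strongest lay on chromosome 20 at 49609631 to 49609894, with a fold of 10.3 ± 0.617 (SD, n = 3). Next came chromosome 10 at 116267001 to 116267650, with a fold of 10.5 ± 2.44 (SD, n = 3), chromosome 8 at 145673557 to 145674181, with 7.14 ± 1.69 (SD, n = 3), and chromosome 19 at 38720347 to 38720730, with 7.93 ± 1.08 (SD, n = 3). Chromosome 17 held 2 of the 12 strongest, at 32526891 to 32527375 with folds from 8.92 to 12.3 in its 3 libraries and at 15732138 to 15732382 with a fold of 10.8 ± 2.14 (SD, n = 3). The others were on chromosome 2 at 198669127 to 198669407, chromosome 13 at 25688386 to 25688764, chromosome 6 at 45534522 to 45534912, chromosome 10 at 5671935 to 5672234, chromosome 8 at 144313775 to 144314000 and chromosome 1 at 160386162 to 160386471. Folds in single libraries ranged from 5.82 to 13.4 over these 12. When the same width and gap limits were imposed on all lists, 188 wild-type-only and 380 depleted-only regions were counted. The limit, 264 bp, is the smallest width of NuMA-depleted replicate 2, whose list kept its 45892 peaks. The other lists shrank, to 34033 and 19336 for NuMA-depleted replicates 1 and 3. Those of wild-type replicates 1, 2 and 3 shrank to 30336, 32229 and 29253. With equal numbers as well, the counts were 296 wild-type-only and 371 depleted-only.

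**Figure D2:**
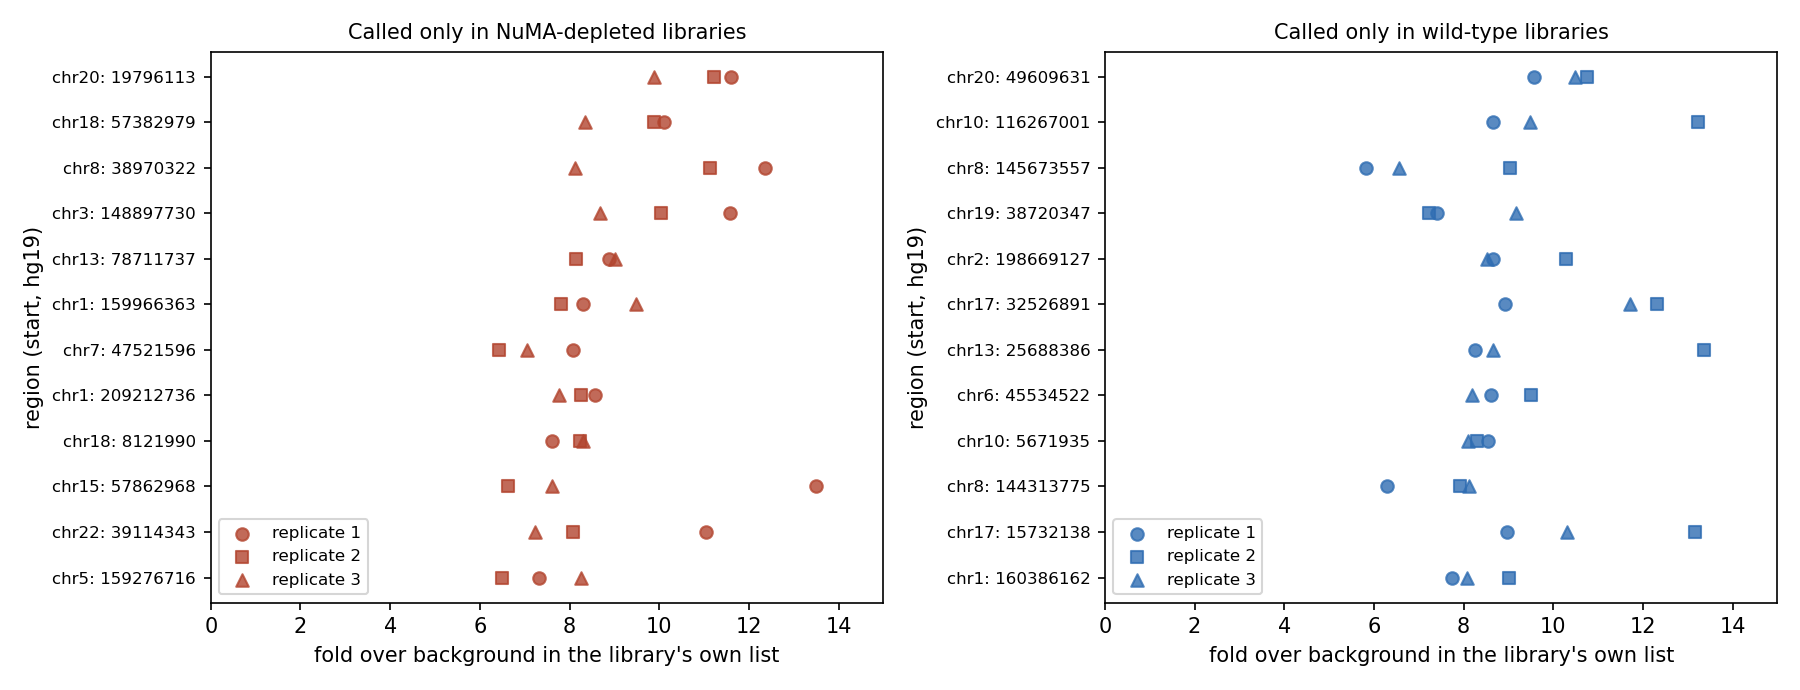
Fold over background of the 12 strongest regions called only in NuMA-depleted libraries (left) and only in wild-type libraries (right), in each of the 3 libraries that called them (marker by replicate), with chromosome and start on hg19. Folds run from 6.43 to 13.5 on the left and from 5.82 to 13.4 on the right.

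Both kinds of group-only region included weak calls within their lists. The lowest list percentile by q among the 3 calls of a depleted-only region had a median of 14.8. That median was 13.7 for wild-type-only regions and 48.0 for regions called in all 6 libraries. The lowest of 3 values is low by construction, and regions of the mixed sets of 3 libraries were not compared. The weakest −log10 q was at least 10 in 24 of the depleted-only and in 28 of the wild-type-only regions. By chromosome, chromosome 16 held 21 depleted-only and 8 wild-type-only regions (Fisher's exact test across regions, p = 0.0227, adjusted over 23 chromosomes 0.445), and chromosome 17 held 12 and 24 (p = 0.0387, adjusted 0.445, exact). Regions are not replicates, and no chromosome passed the adjusted threshold.

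**Figure D3:**
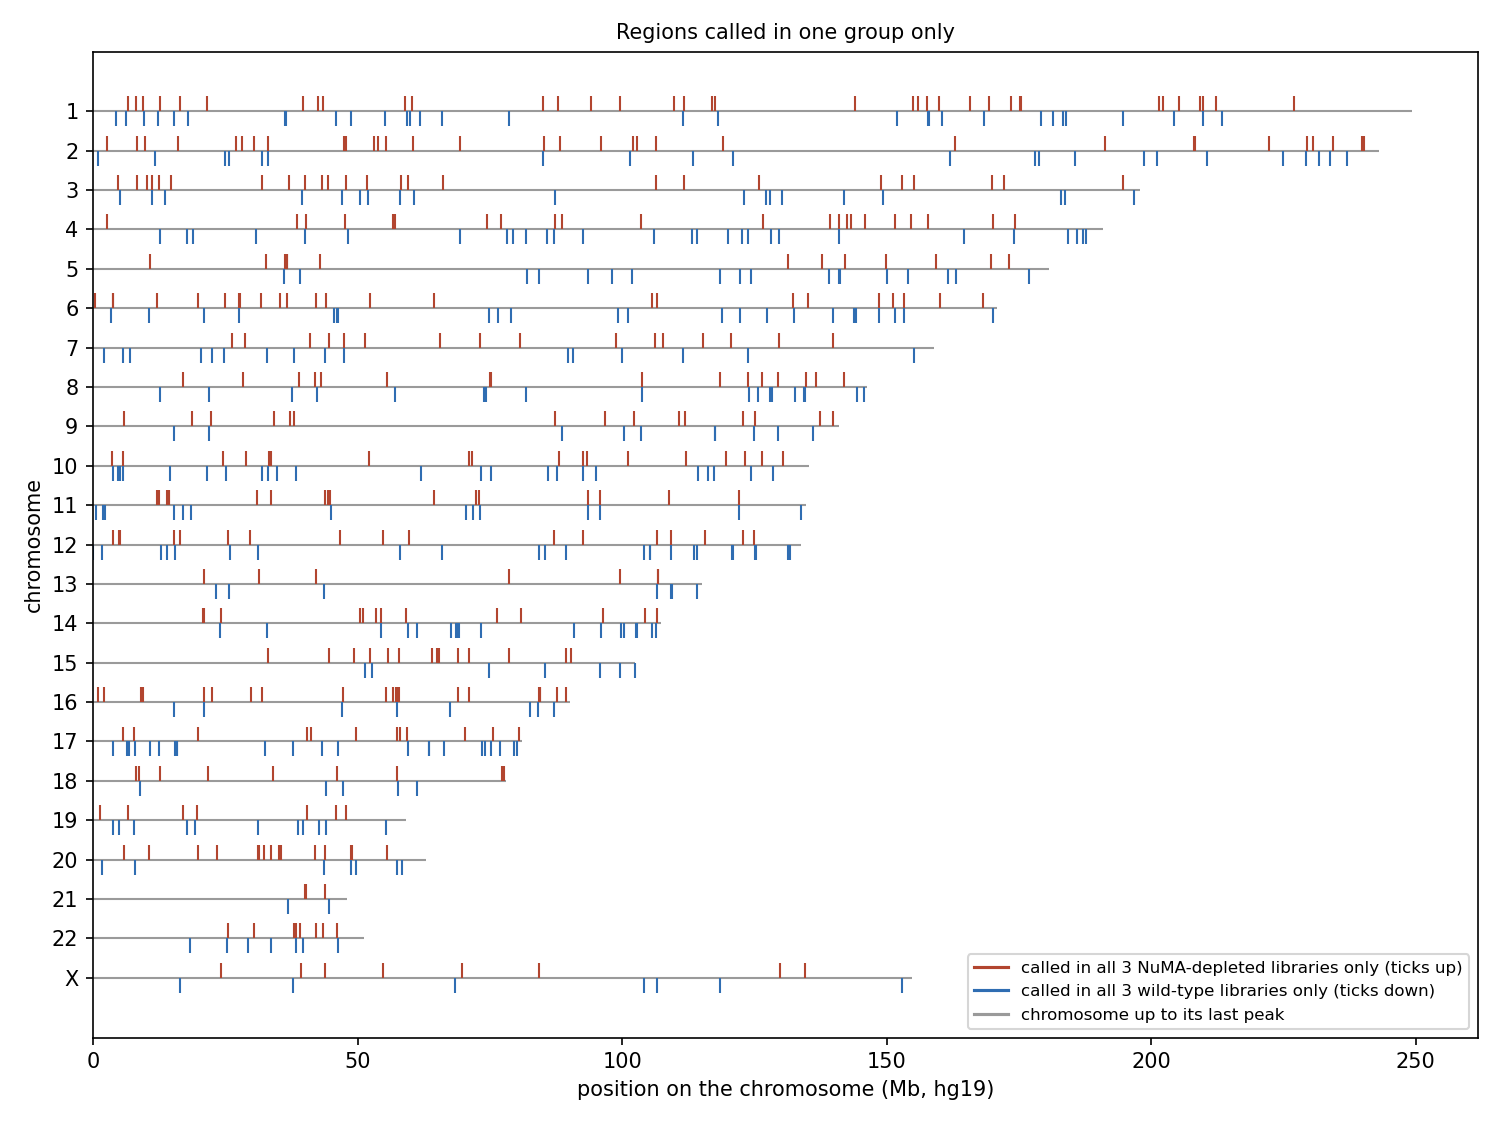
Positions (Mb, hg19) of the 368 regions called only in the 3 NuMA-depleted libraries (ticks up) and the 349 called only in the 3 wild-type libraries (ticks down) along chromosomes 1 to 22 and X, each drawn to its last peak. Both kinds occur on all 23 chromosomes.

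Whether the groups share more of their own regions than any other set of 3 libraries depended on how many peaks each list contributed. With all deposited peaks, the 18 sets of 3 libraries that mix the groups had between 11 and 1270 regions of their own, and the highest count belonged to NuMA-depleted replicates 1 and 2 with wild-type replicate 2. By the planned comparison of 10 splits, both group counts together were 717. Of the 10 splits, 4 gave as many, the real one included, and the highest of the others gave 1282. A division of the mixed sets by NuMA-depleted replicate 3 was not planned. Among the 9 mixed sets that include NuMA-depleted replicate 3, counts ran from 11 to 111, below the 368 of the NuMA-depleted group. Among the 9 mixed sets without it, counts ran from 106 to 1270, a range that holds the 349 of the wild-type group. With a −log10 q of at least 5 the groups had 318 and 271 and the highest mixed set 1424. With the strongest 21783 peaks of each library, 440 regions were called only in the NuMA-depleted and 339 only in the wild-type libraries, and the mixed sets had between 92 and 233. Both group counts were then higher than all 18 mixed counts, but not when absence also needed no deposited peak of any strength, with 62 and 35 against 1 to 115 in the mixed sets. The 9 mixed sets that include NuMA-depleted replicate 3, as the NuMA-depleted group does, had 1 to 12 under that rule. The 9 mixed sets without that replicate, like the wild-type group, had 5 to 115, a range that holds the wild-type 35. Without NuMA-depleted replicate 3, and with 32503 peaks from each of the other 5 libraries, 1323 regions were called only in NuMA-depleted replicates 1 and 2, against 468 to 840 for the other pairs, and 887 only in the 3 wild-type libraries, against 352 to 752 for the other sets of 3.

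Leaving out a library weakens the requirement, so higher counts follow by construction, but the rise differed with the library left out. Depleted-only regions numbered 585, 432 and 2691 without NuMA-depleted replicates 1, 2 and 3. They numbered 567, 703 and 532 without wild-type replicates 1, 2 and 3. Wild-type-only regions numbered 610, 1287 and 370 without NuMA-depleted replicates 1, 2 and 3, and 786, 616 and 976 without wild-type replicates 1, 2 and 3. Of the 440 depleted-only regions at equal numbers, 62 (14.1%) had no deposited peak in any wild-type library, and of the 339 wild-type-only regions 35 (10.3%) had none in any NuMA-depleted library. The remainder were called in the other group too, below the strongest 21783 peaks. All 12 of the strongest wild-type-only regions and 8 of the 12 strongest depleted-only regions were among those group-only by both counts.

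**Figure D4:**
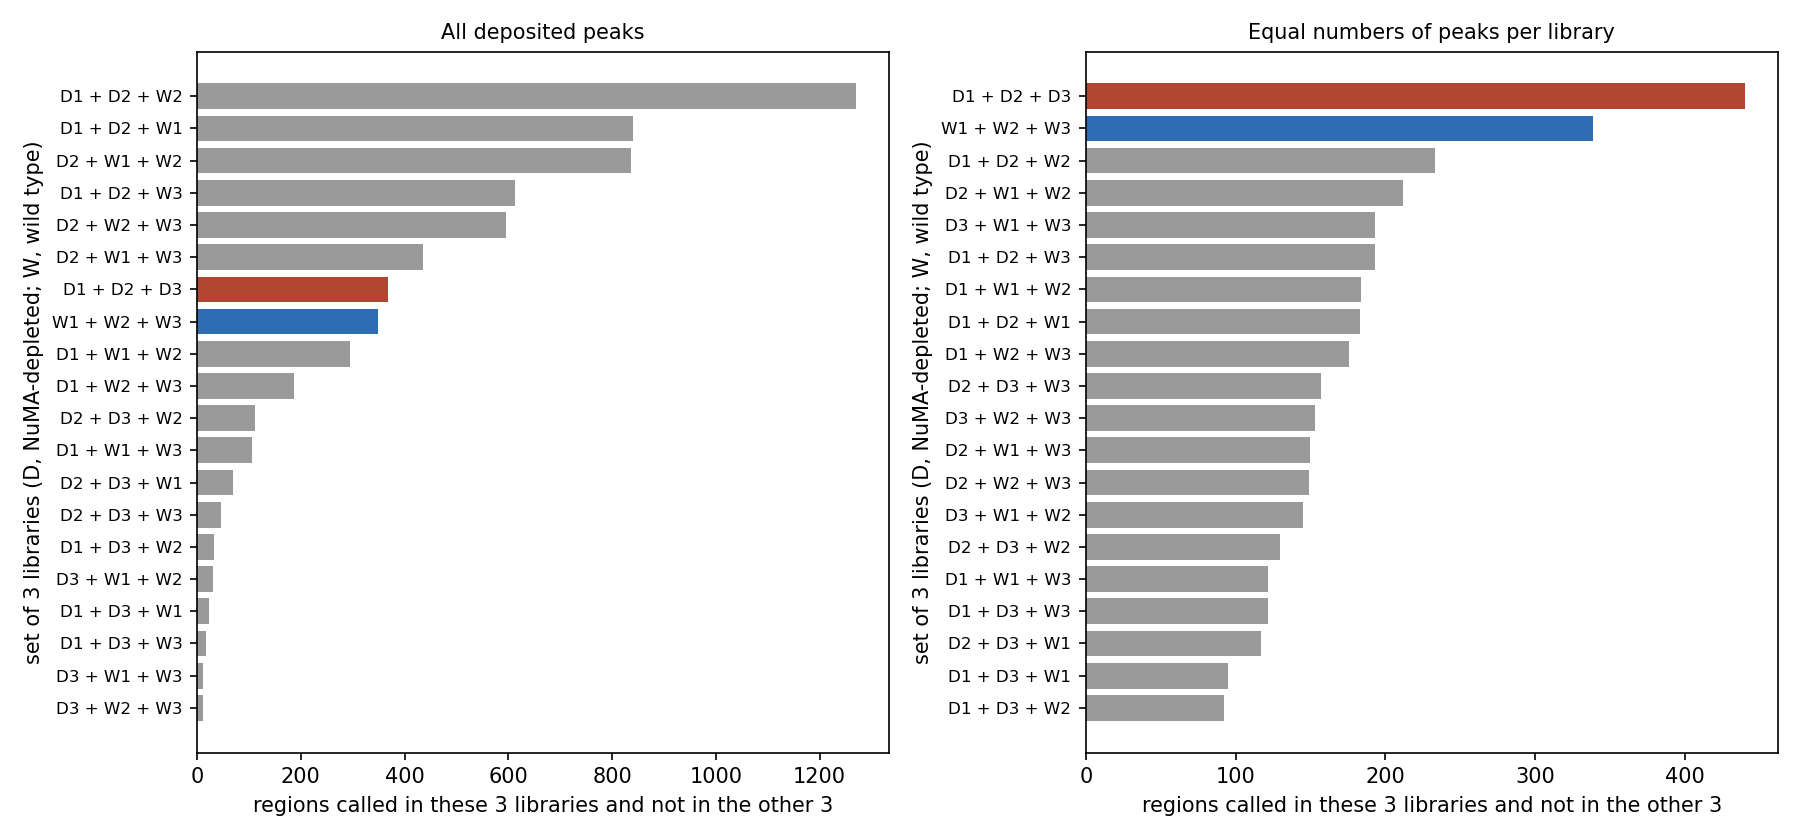
Number of regions called in a given set of 3 libraries and in none of the other 3 (bars), for all 20 sets, with all deposited peaks (left) and with the strongest 21783 peaks of each library (right). D and W are NuMA-depleted and wild-type replicates, and grey bars are mixed sets. At equal numbers the NuMA-depleted set, 440, and the wild-type set, 339, exceed the highest mixed set, 233.

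With all deposited peaks, libraries of the same group overlapped little more than libraries of different groups. The mean Jaccard index was 0.505 within groups and 0.496 between groups. The 3 wild-type pairs had indices of 0.559, 0.551 and 0.558. NuMA-depleted replicates 1 and 2 had 0.561, and the pairs with NuMA-depleted replicate 3 had 0.442 and 0.360. An index cannot exceed the shorter covered length divided by the longer, so lists of unlike length limit it. NuMA-depleted replicates 3 and 2 covered 11.1 and 28.4 Mb. The difference of 0.00873 was reached or exceeded in 3 of the 10 splits of the 6 libraries, and it was -0.0179, -0.0152 and -0.0168 without wild-type replicates 1, 2 and 3, and 0.0317, 0.0363 and 0.0343 without NuMA-depleted replicates 1, 2 and 3. With equal numbers of peaks it was 0.0194, the highest of the 10 splits, and the next highest was 0.00782.

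The share of closely spaced peaks was lower in the 3 NuMA-depleted than in the 3 wild-type libraries, in a design too small to pass the threshold. Peaks with a gap under 1 kb to the next peak made up 2.45% ± 0.505 (SD, n = 3) of the lists of NuMA-depleted and 3.50% ± 0.518 (SD, n = 3) of those of wild-type libraries. The result had p = 0.1 (exact permutation test, two-sided), the smallest this design allows. The groups only just separated, with 2.97% in NuMA-depleted replicate 1 and 3.003% in wild-type replicate 3. The groups overlapped once all lists had the same number of peaks, with 1.05% ± 0.801 (SD, n = 3) against 0.956% ± 0.131 (SD, n = 3), where NuMA-depleted replicate 3 had 1.96% and replicates 1 and 2 had 0.707% and 0.477%. They overlapped also with common width and gap limits, with 1.96% ± 0.536 (SD, n = 3) against 2.32% ± 0.181 (SD, n = 3). With a −log10 q of at least 5 they overlapped at 1.73% ± 0.527 against 2.39% ± 0.418 (SD, n = 3 each, exact p = 0.2). With a 5 kb gap they overlapped at 8.56% ± 2.66 against 9.41% ± 1.27 (SD, n = 3 each, exact p = 0.8). They did not overlap when summits under 1 kb apart were counted instead, with 0.978% ± 0.309 against 1.81% ± 0.304 (SD, n = 3 each, exact p = 0.1). Median peak width was 480.0 ± 49.3 bp (SD, n = 3) in NuMA-depleted and 449 ± 17.2 bp (SD, n = 3) in wild-type libraries, with p = 0.5 in the exact test. The smallest width in a list was 213, 264 and 223 bp in the NuMA-depleted and 203, 190 and 222 bp in the wild-type libraries, and the median width above that limit was 247 ± 26.0 bp and 244 ± 1.53 bp (SD, n = 3 each). Without NuMA-depleted replicate 2 the difference in median width was 2.67 bp.

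No redistribution of peaks along the genome was detected at these sample sizes. The share of a library's peaks on a chromosome separated the groups on 0 of the 23 chromosomes, where chance gives 10% of chromosomes, and the smallest adjusted p was 1 (exact permutation test, two-sided, Benjamini-Hochberg). As the exact p cannot go below 0.10 here, no chromosome could have passed an adjusted 0.05, so the adjusted values cannot decide. At equal numbers of peaks 1 chromosome, chromosome 10, separated the groups, by 0.193 percentage points more in NuMA-depleted libraries (exact p = 0.1, adjusted 1); it is named after its value was seen. Chromosome 1 held 9.80% ± 0.150 (SD, n = 3) of peaks in NuMA-depleted and 9.74% ± 0.0763 (SD, n = 3) in wild-type libraries, and the X chromosome 1.96% ± 0.0950 and 2.03% ± 0.0528 (SD, n = 3 each). Among 2022 bins of 1 Mb, 0 changed in peak density by limma, the smallest adjusted p was 0.872, and 114 bins had an unadjusted p under 0.05. The bin with the smallest p, from 193 to 194 Mb on chromosome 3, held a mean of 15.7 peaks in NuMA-depleted and 22 in wild-type libraries, a log2 difference of -0.51 (SE 0.138) in its share of peaks, with an adjusted p of 0.872 by limma. That bin was picked after its value was seen.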

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

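The 500 bp windows, the common width and gap limits, the −log10 q of at least 15, the mixed thresholds for presence and absence, the cover of 50% of the merged region, summit distances, widths above the smallest width and the combinations of settings were chosen after seeing the data. The difference in peak number between NuMA-depleted and wild-type libraries, -183, turned to 771 with a −log10 q of at least 5 and to 2481 with common width and gap limits, and ranged from -5439 to 6616 when each library was left out. The difference in covered length, 1.31 Mb, ranged from -2.88 to 5.80 Mb when each library was left out, and that in Jaccard overlap from -0.0179 to 0.0363. The difference in closely spaced peaks turned from -1.04 to 0.0933 percentage points at equal numbers of peaks and kept its sign under the other 12 alternatives. The groups nevertheless overlapped with a −log10 q of at least 5 (difference -0.659), with a 5 kb gap (-0.849) and with common width and gap limits (-0.366). Depleted-only regions, 368, numbered 2967 when 2 of 3 libraries sufficed, 195 when presence needed a −log10 q of at least 5 and absence no peak at all, 76 with a −log10 q of at least 15, 62 when presence needed 1 of the strongest 21783 peaks and absence no peak at all, 1323 without NuMA-depleted replicate 3 at equal numbers, and 432 to 2691 when each library was left out. Wild-type-only regions, 349, numbered 1677, 180, 49, 35, 887 and 370 to 1287 under the same settings and 188 with common width and gap limits. The planned half-overlap rule moved nothing, since each peak lies inside its merged region. Chromosomes whose groups did not overlap numbered 0 with all peaks, 1 at equal numbers, 1 with every pair on the same side under the replicate block, and 1 to 2 when each library was left out. No bin passed the threshold under any alternative, where the smallest adjusted p by limma ranged from 0.0810 to 0.993 over 21 alternatives. The cause of these changes was not tested, though fewer libraries give a weaker requirement by construction. No pairing by replicate number was seen. Over bins the deviations of same-numbered libraries from their group means correlated at -0.077, 0.092 and 0.007. With 3 libraries per group these values cannot exclude a pairing or a shared preparation. With a replicate block the differences stayed the same by construction, the exact p (smallest possible 0.25) was 1, 0.75, 0.75 and 0.25 for peak number, covered length, median width and closely spaced peaks, and 0 bins passed by limma. Alternatives on promoters and genes were not run, as no hg19 gene annotation was used here. Depth in reads is unknown, so which calls depth limits was not tested.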

Other observations

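Relative depth, and the 10 splits of the libraries for group-only regions and for overlap, were planned. How depth, enrichment, clustering along chromosomes, peak numbers and splits were read as tests of explanations was set only after the results were seen. The splits for bins and for chromosome shares were not planned. The settings with 500 bp windows and common limits were chosen after seeing the data but before their own outcomes were known.

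Shares of peaks per chromosome separated the libraries most often along a split that is not the study's, picked as the highest of the 10 splits after their values were seen. NuMA-depleted replicates 1 and 2 and wild-type replicate 3 had a higher share of peaks than each of the other 3 libraries on 5 chromosomes, 15, 16, 18, 20 and 22, and a lower share on 4 chromosomes, 5, 6, 8 and X. On chromosome 22 the shares were 2.35%, 2.37% and 2.36% in those 3 libraries and 1.96%, 2.11% and 2.24% in NuMA-depleted replicate 3 and wild-type replicates 1 and 2. This split separated 9 of 23 chromosomes, where the real split separated 0 and the other 8 splits 0 to 4. The regions from 15 to 16 Mb of chromosome 17 held 4 of the wild-type-only regions, the most of any 1 Mb bin, and 10.1% of 10000 random draws from regions called in exactly 3 libraries had a bin as dense.

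NuMA-depleted replicate 3 had 21783 peaks, the fewest of the 6. Lower depth is argued against by its relative depth of 1.11, above all 3 wild-type libraries with more peaks. Fewer accessible regions after NuMA depletion stays open only as a difference between the groups. The other NuMA-depleted libraries had 38466 and 45892 peaks, both above the wild-type 35563 ± 3091 (SD, n = 3) and the latter beyond that spread. Both were also deeper than the wild-type libraries. Replicate 1 had more peaks than replicate 3 at a lower relative depth, 1.07. All 3 share the depletion label, which by itself does not set replicate 3 apart from replicates 1 and 2. The extent of depletion was not checked here. Lower enrichment of fragments over background in replicate 3 also stays open. Its median fold at the 17009 shared regions was 6.43, against 7.65 to 8.76 in the other 5 libraries, but a fold is each list's own value.

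At equal numbers of peaks the 440 depleted-only and 339 wild-type-only regions exceeded the 18 mixed sets, which reached 233. Neither exceeded all of them when any deposited peak of the other libraries counted against absence, with 62 and 35 against at most 115. The 62 exceeded the 9 mixed sets that also include NuMA-depleted replicate 3, at most 12. The 35 lay inside the range of the 9 mixed sets without that replicate, 5 to 115. Interval widths that differ between libraries are argued against, since with 500 bp windows on summits the smaller of both counts was 352 against at most 238 in mixed sets, and with common width and gap limits it was 296 against at most 209. Segments gained or lost in 1 of the cell populations stay open, as the share of depleted-only regions with another within 1 Mb, 40.2%, lay inside the central range of 31.4% to 42.5% of 10000 random draws, and that of wild-type-only regions, 30.7%, inside 23.9% to 36.3%, in a test whose power is unknown. For both the depleted-only and the 339 wild-type-only regions depth and group cannot be told apart, because 0 wild-type libraries were as deep as the shallowest NuMA-depleted library. NuMA depletion, or another difference between the cell populations or their preparation, may also underlie both sets and stays open as a hypothesis.

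The share of closely spaced peaks was lower in each NuMA-depleted library, at 1.96% to 2.97% against 3.003% to 4.04% in the wild-type libraries. With common width and gap limits the highest NuMA-depleted library reached 2.42%, above 2 wild-type libraries at 2.24% and 2.19%, while NuMA-depleted replicates 1 and 3 stayed below all 3 at 2.07% and 1.37%. At equal numbers NuMA-depleted replicate 3, whose list sets that number and loses no peak, had 1.96%, above the 0.808% to 1.06% of the wild-type libraries, while replicates 1 and 2 had 0.707% and 0.477%. By more than 2 wild-type SDs below the lowest wild-type library (SD 0.181 and 0.131, n = 3), replicate 3 with common limits argues against those limits and replicate 2 at equal numbers against peak number, each as the only cause in that library. Width and gap limits may account for replicate 2 and peak number for replicate 3, and both stay open for replicate 1, with NuMA depletion as an untested possibility.

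The 6 libraries can be split into 3 and 3 in 10 ways, which is too few for a share under 0.05. With all deposited peaks the real split gave 717 group-only regions, and 4 of the 10 splits gave as many, the highest of the others 1282. At equal numbers the real split gave 779, 1 of the 10 splits gave as many, and the highest of the others was 426. For the Jaccard difference 3 of the 10 splits reached the real 0.00873, with 0.0224 as the highest other. For bins tested with limma all 10 splits gave 0, the highest of the others being 0, with 42 to 163 bins at an unadjusted p under 0.05 in the other splits.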
